A study of Homo sapiens with 12 samples.

How the data were processed

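RNA of 8 cell lines was measured on 12 two-channel expression arrays. Per the labels, the cell line RNA carried Cy5 and a common reference of whole human RNA carried Cy3 on each array, with no swapped array. The deposited table holds 1 value per feature and array for 45220 features, with no missing value and no signal intensity. The values were taken as log2 ratios that the authors deposited, because they run from -10.71 to 9.61 around array medians near 0. The log base, the background correction, the normalization and the direction of the ratio are not given in the sources used here. Array medians over all features lay between 0 and 0.042 apart from MiaPaca2 DMSO replicate 1 at -0.001. Because the reference carried Cy3 and the cell line Cy5, cell line over reference was taken as the likely direction. A test planned for it was not decisive: 15 of 23 genes of differentiated tissues had a mean below 0 (exact binomial test, two-sided, p = 0.21). ALB, a liver gene, lay between -7.90 and -5.79 on all 12 arrays, and 11 of the 23 genes were below 0 on all arrays. EPCAM and KRT8 stood at 3.42 and 1.34 in HT29, and VIM at 1.70 in Panc1 and 2.05 in MiaPaca2 with the DMSO label, with ZEB1 at 0.02 and 1.46.

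Features were named through the platform annotation given with the table. Of the features, 31332 had 1 gene symbol, 93 several and 13795 none, and those with several or none were left out. Gene identifiers of 31291 named features matched the RefSeq table of assembly GRCh38.p14, which was used for names only, and 41 kept the annotation symbol. A gene was the mean over its features, giving 18334 genes, 7759 of them with more than 1 feature. Exact zeros made up 0.17% of named values and were kept. Without intensities, features near background could not be told from bright ones, and ratios of dim features are less reliable.

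Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). Pairs of groups were compared in a fit of all 12 arrays in 9 groups of cell line and media label, where only the DMSO-labelled pairs gave residual degrees of freedom, 3 in all, with a prior of 5.23. Pancreatic and colorectal lines were compared on 8 line means. That split follows the catalogued origin of the established lines, not the labels. Called means an adjusted p under 0.05, and differences are log2 values of the first group minus the second. A planned fit of every gene on F3 across lines, and planned correlations of F3 with gene lists, were left out because F3 values formed separate clusters.

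The rule for named genes was fixed before the data were examined. F3 was always named. In each comparison the 5 highest and 5 lowest differences among called genes whose groups did not overlap were named, leaving out sex-linked XIST and Y genes and symbols of hypothetical loci, and up to 3 called members of each list with the smallest adjusted p. CDH1, EPCAM, VIM, ZEB1, TFPI, PLAU, PLAUR, F2RL1, CDX2 and MUC5AC were to be given whatever their p, as was 1 gene not reported here. A first version of the selection also left out antisense and other noncoding symbols that the rule does not name, and it was brought back to the rule after results had been seen, which added TLR8-AS1. The 14 lists, fixed at the same time, held 390 entries, of which 363 were measured, 2 through a synonym. They cover coagulation and fibrinolysis, epithelial, mesenchymal, pancreatobiliary and gastric, intestinal, exocrine and endocrine pancreas, other differentiated tissues, proliferation, hypoxia and glycolysis, EGFR and MAPK, NF-kB and chemokines, interferon, Wnt, and stress and xenobiotic response. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. The second form also takes its degrees of freedom from the residual ones of the fit, 3 for groups and 6 for line means. It therefore has little power here, and a list that fails it is not shown to fail through correlation.

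The scripts were tested on simulated data with 200 changed genes among 18334 in 5 draws. A log2 change of 1 was recovered for 5.67% of genes in the Panc1 and HT29 comparison and a change of 2 for 86.2%. The real comparison called 6831 genes, and recovery depends on the share of changed genes, so these percentages do not give its sensitivity. In the comparison of pancreatic with colorectal lines a change of 2 was recovered for 43.3% and of 3 for 73.5%. Alternatives were another centring or quantile normalization, the most variable feature of a gene, filters on SD and on size of difference, robust eBayes, other groupings of the arrays, the replicate number as a block, and leaving out each array or line. Figures were drawn with matplotlib 3.10.9.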

Results

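RNA of 8 human tumour cell lines was hybridised to 12 two-channel arrays, each against a common reference of whole human RNA. The series title concerns tissue factor, the cell surface protein encoded by F3 that starts blood coagulation, in xenografts of pancreatic cancer. Capan2, HPAC, HPAFII, HCT-116 and SW620 had 1 array each and no media label. HT29 and Panc1 had 2 arrays each, all with a DMSO label. MiaPaca2 had 2 arrays with the DMSO label and 1 without. The design text calls all 8 lines pancreatic, whereas HCT-116, HT29 and SW620 are established lines catalogued as colorectal, and they are called colorectal here. Values are the deposited ratios, taken as log2 of cell line over reference, a direction that is likely but not stated. No separate cultures are named for the arrays of a group, so p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision. Arrays of one group correlated across genes at 0.874 to 0.941, and arrays of different lines at 0.37 to 0.731.

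In the likely direction, F3 was far above the reference in 3 of the pancreatic lines, and with the ratio turned every sign and the order of lines would turn. Its log2 ratio was 6.87 in HPAFII, 5.91 in HPAC and 5.72 in Capan2, each on a single array. With quantile normalization these became 5.12, 5.22 and 5.31, so the order of the 3 lines turned. The colorectal lines HCT-116 and HT29 followed at 1.89 and 1.19, and SW620 lay at -0.39. Panc1 had a mean of -1.03 and MiaPaca2 with the DMSO label a mean of -0.36, while the MiaPaca2 array without a media label gave -1.40. F3 was lower in Panc1 than in HT29, with a limma log2 difference of -2.23 (SE 0.269, n = 2 arrays each, adjusted p = 0.0004016). It was also lower in MiaPaca2 than in HT29, by a log2 difference of -1.55 (limma, adjusted p = 0.003078). The 0.68 between MiaPaca2 and Panc1 did not pass the threshold (limma, adjusted p = 0.1252), and was 0.38 without Panc1 replicate 1, 0.97 without Panc1 replicate 4 and 0.33 with the 3 MiaPaca2 arrays as one group. F3 was read by a single array feature.

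**Figure D1:**
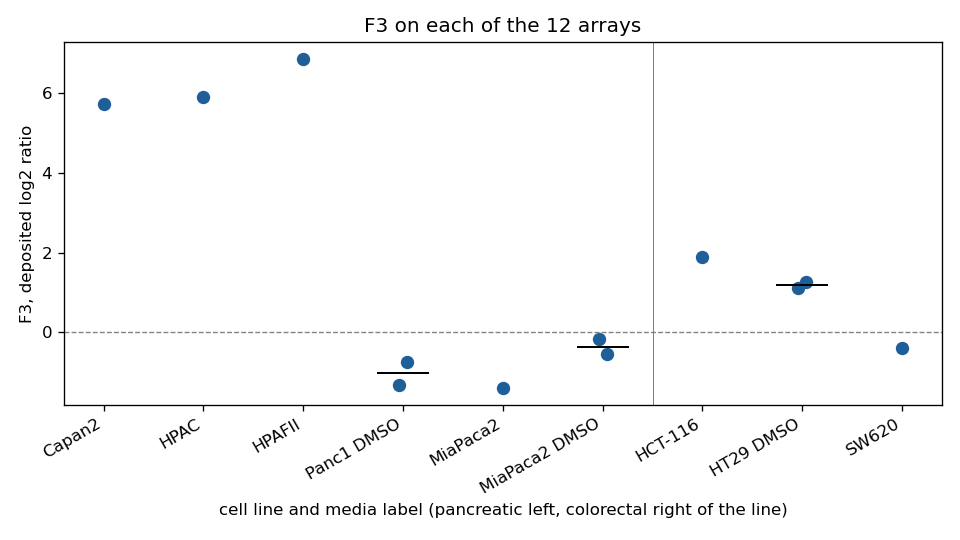
Each point is the deposited log2 ratio of F3 on 1 array, with cell line and media label on the horizontal axis and horizontal bars at the mean of groups with 2 arrays. Capan2, HPAC and HPAFII lie at 5.72 to 6.87, in an order that turns with quantile normalization, and the remaining arrays at -1.40 to 1.89.

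The relation of F3 to other genes across lines was not tested. The line values of F3 fell into separate clusters, with a gap of 3.84 log2 units between the 5 lower and 3 higher lines, wider than the range within either, and neither cluster held 6 lines.

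The DMSO-labelled pairs allowed lines to be compared with replicate error. In Panc1, epithelial genes were lower and mesenchymal genes higher than in HT29. Of 29 measured epithelial genes, 24 were lower and 2 higher, and of 30 mesenchymal genes 17 were higher and none lower, or 13 and 1 with quantile normalization, where the mesenchymal median fell from 0.98 to 0.47. MAL2, a membrane protein of apical transport, had the lowest difference at -10.30 (SE 0.265). The adhesion genes CDH1 and EPCAM differed by -4.62 and -4.34, and RAB25 by -5.10. The intermediate filament gene VIM was higher by 6.41 (SE 0.25), the matrix enzyme gene LOXL2 by 5.22, CDH2 by 3.88 and the repressor gene ZEB1 by 1.78. In the camera test with a preset correlation, the epithelial list had an adjusted p = 1.359e-11 and the mesenchymal list an adjusted p = 3.206e-06, but with an estimated correlation both had an adjusted p = 0.4276. Adjusted over the list alone, 24 epithelial genes were lower and 4 higher, and 18 mesenchymal genes were higher.

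Among 34 measured genes of coagulation and fibrinolysis, 10 were higher in Panc1 than in HT29 and 3 lower, also when adjusted over the list alone. Over all 18334 genes, 3925 were higher and 2906 lower, so a list can hold several called genes without standing out. PLAU, which encodes the plasminogen activator urokinase, had the highest difference of all named genes at 7.94 (SE 0.305, limma, adjusted p = 2.603e-06). THBD, the thrombin receptor thrombomodulin, was higher by 7.16 and TFPI2 by 4.15, although TFPI2 remained below the reference in both lines. F3, F5 and S100A10 were lower. TFPI, the inhibitor of the tissue factor pathway, differed by -0.12 with features that disagreed in sign, and PLAUR, the urokinase receptor, by -1.32, and neither passed the threshold (limma, adjusted p = 0.7988 and 0.07748). Without HT29 replicate 4, PLAUR passed at -2.15 and TFPI stood at 0.22, and without HT29 replicate 2 they stood at -0.49 and -0.47. The list as a whole did not pass the camera test (adjusted p = 0.2481, and adjusted p = 0.7077 with an estimated correlation). With quantile normalization 7 were higher and 4 lower, and the list median turned from 0.31 to -0.18.

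In the intestinal and the pancreatobiliary and gastric lists, more genes were lower in Panc1 than higher, and many were not called. The intestinal list had 14 of 26 genes lower and 1 higher, with KRT20 at -4.74 and VIL1 at -3.90, and the pancreatobiliary and gastric list had 12 of 29 lower and 5 higher, with LYZ at -8.55 and S100P at -5.29. These lists had camera adjusted p = 3.206e-06 and 0.001371, and both had an adjusted p = 0.4916 with an estimated correlation. The interferon list had 11 of 23 genes lower and 2 higher, with IFI27 at -3.27 and BST2 at -3.03 (camera adjusted p = 0.01723, and adjusted p = 0.5916 with an estimated correlation). CFTR was at -5.00 as a mean of 11 features, whose differences ran from -6.06 to 0.072. The chemokine gene CCL2 was higher by 7.78 and ICAM1 by 4.22, while LCN2 was at -4.50; the list of NF-kB targets and chemokines had 9 of 23 genes higher and 5 lower. The metallothionein gene MT2A was higher by 6.26 and the reductase gene AKR1B10 lower at -5.76, in a stress list with 13 of 29 genes higher and 6 lower. The hypoxia list had 6 of 24 genes higher, BNIP3 by 5.16, and 2 lower. The proliferation list had 9 of 29 higher and 2 lower, the Wnt list 3 of 18 higher and 7 lower with AXIN2 at -2.71, and the EGFR and MAPK list 10 of 27 higher and 5 lower with TGFA at -3.09. Genes of exocrine and endocrine pancreas went both ways, with SPINK1 at -6.39 and CHGB higher by 4.26, and 2 of 19 were higher and 3 lower. Of 23 genes of other differentiated tissues, 1 was higher and 1 lower. Adjusted p of these lists ranged from 0.0548 for Wnt targets to 0.8891 for the EGFR and MAPK list in the camera test. The EGFR and MAPK list had a mean of 0.061 and a median of 0.087 that became -0.12 and -0.093 with quantile normalization, which also turned the medians of the NF-kB list from 0.16 to -0.25, with 6 genes higher and 5 lower, and of the hypoxia list from 0.30 to -0.068, with 5 higher and 4 lower. The exocrine and differentiated tissue lists had a median of 0.091 and 0.027 and a mean of -0.20 and -0.029. With quantile normalization the differentiated tissue list had 4 genes lower, none higher and a median of -0.40, and 3 pancreatobiliary genes and no intestinal gene were higher. With arrays shifted to a median of 0 the differentiated tissue median was -0.0082. Adjusted over the list alone, counts were 3 higher and 11 lower for the interferon list, 10 and 5 for NF-kB targets and 10 and 6 for EGFR and MAPK genes, none for differentiated tissues, and as given for the other lists.

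Outside the lists, the helicase gene DDX43 was higher in Panc1 by 7.65 and ANGPTL4, an inhibitor of lipoprotein lipase, by 7.54. TSPAN8 was lower at -8.82, the glycosyltransferase gene GALNT3 at -8.69 and RFX6 at -7.55, with an SE of 1.02 for RFX6. In all, limma called 6831 of 18334 genes, 3925 higher and 2906 lower, and 5089 of them differed by at least 1 log2 unit. The count was 4135 without Panc1 replicate 1 and 4495 without Panc1 replicate 4.

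In MiaPaca2 with the DMSO label, most epithelial genes were lower than in HT29. Of 29 genes, 26 were lower and none higher, with MAL2 at -10.41, EPCAM at -9.0 (SE 0.253) and CDH1 at -7.02 (SE 0.3). VIM was higher by 6.76, LOXL2 by 6.06, the collagen gene COL5A2 by 5.22 and ZEB1 by 3.22, and 13 of 30 mesenchymal genes were higher with none lower. With quantile normalization 10 mesenchymal genes were higher and 2 lower, with a median of 0.20 rather than 0.53, and 1 was lower with arrays shifted to a median of 0. The camera test gave an adjusted p = 4.298e-17 for the epithelial and 0.0002031 for the mesenchymal list, and an adjusted p = 0.328 for each with an estimated correlation. The intestinal list had 15 of 26 genes lower and none higher, the pancreatobiliary and gastric list 13 of 29 lower and 2 higher, and the interferon list 12 of 23 lower and 2 higher. KRT20 was at -4.93, LYZ at -8.51 and IFI27 at -4.65. Their camera adjusted p were 1.644e-07, 0.0007459 and 0.0003815, and with an estimated correlation adjusted p = 0.328, 0.334 and 0.328.

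Genes of NF-kB signalling and chemokines were higher in MiaPaca2 than in HT29 for 12 of 23 members and lower for 4. CXCL1 was higher by 6.58, CXCL5 by 3.90, and IL18 was at -4.50. This list and the proliferation list, with 11 of 29 genes higher and 1 lower, had camera adjusted p = 0.009411 and 0.01529, and adjusted p = 0.328 and 0.4697 with an estimated correlation. Of 34 coagulation and fibrinolysis genes, 10 were higher and 4 lower, with PLAU higher by 6.20, the thrombin receptor gene F2R by 4.27 and TFPI by 1.08, and the cofactor gene F5 at -4.10. With quantile normalization 5 were higher and 4 lower, and the list median turned from 0.12 to -0.11. The TFPI difference fell short of the threshold without MiaPaca2 replicate 1 (0.76) or HT29 replicate 2 (0.74). PLAUR differed by -0.54 and did not pass (limma, adjusted p = 0.4701), with 0.29 without HT29 replicate 2 and a call at -1.37 without HT29 replicate 4. The EGFR and MAPK list had 11 of 27 genes higher, EPHA4 by 6.24, and 7 lower. The stress list had 12 of 29 higher and 5 lower, the hypoxia list 7 of 24 higher, or 4 with quantile normalization, and 2 lower, the Wnt list 2 of 18 higher and 7 lower, the exocrine and endocrine list 3 of 19 higher and 3 lower, and the differentiated tissue list 2 of 23 higher and 1 lower. Quantile normalization moved the hypoxia median from 0.33 to 0.0018 and the exocrine median from -0.059 to 0.0023, and left 2 differentiated tissue genes lower and none higher, with a median of -0.32 rather than -0.067. Camera adjusted p of these lists and of the coagulation list were 0.05952 to 0.5339. Further genes at the extremes were PTX3, OGFRL1, CAVIN2 and GAL, higher by 6.65 to 6.75, and GALNT3 and TSPAN8, at -9.40 and -9.02. Adjusted over the list alone, 27 epithelial, 13 interferon, 5 coagulation, 6 stress and 2 proliferation genes and 1 mesenchymal gene were lower, 15 NF-kB, 13 EGFR and MAPK, 14 stress and 3 pancreatobiliary genes were higher, no differentiated tissue gene passed, and other counts were as given. Limma called 5851 genes, 3191 higher and 2660 lower.

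Both comparisons used the same HT29 arrays. They shared 4056 called genes, of which 2132 were higher in both, 1808 lower in both and 116 opposite. Independent lists of these sizes would share 683.1 higher and 421.6 lower. The log2 differences correlated across genes at 0.723, against 0.505 in simulated arrays with no effect, and their covariance was 1.09 against 0.0427. The simulated arrays held noise and no line differences, and the independent lists took no account of the shared arrays. The expression of HT29 itself enters both differences, so neither number shows what unrelated lines would give. Differences that shared Panc1 or MiaPaca2 instead correlated at 0.4365 and 0.3057, with covariances of 0.503 and 0.333. Genes are not independent replicates, and how much of the excess comes from HT29 was not tested.

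**Figure D2:**
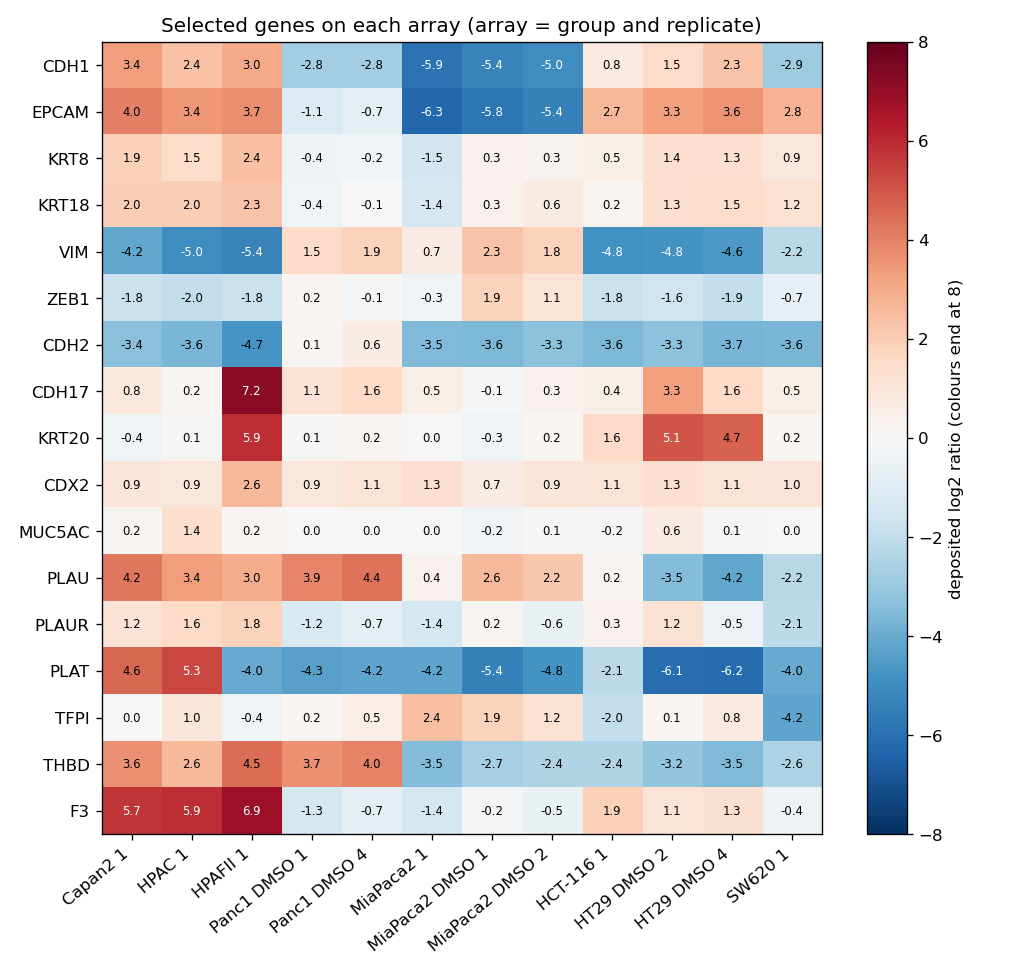
Rows are genes and columns are the 12 arrays, named by group and replicate, and colour and printed value give the deposited log2 ratio. CDH1 and EPCAM are lowest on the 3 MiaPaca2 arrays, VIM is above 0 on the Panc1 and MiaPaca2 arrays, and PLAT is above 0 in Capan2 and HPAC alone.

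Members of the epithelial, mesenchymal and coagulation lists differed between MiaPaca2 and Panc1, where 3422 of all 18334 genes were called. Of these lists only the epithelial one passed the camera test, and only at the preset correlation. The mesenchymal and coagulation lists each had a camera adjusted p = 0.4797. EPCAM was lower in MiaPaca2 at -4.66 (SE 0.253, limma, adjusted p = 1.835e-05), CDH1 at -2.40 and the protease inhibitor gene SPINT2 at -3.85, while the epithelial transcription factor gene EHF was higher by 4.83. Of 29 epithelial genes, 11 were lower and 1 higher. Mesenchymal genes split, 6 of 30 higher and 9 lower, with TGFBI at -4.63, CDH2 at -3.79 and COL1A1 at -2.54, and VIM differed by 0.35 without passing (limma, adjusted p = 0.3892), or by -0.10 when the 3 MiaPaca2 arrays formed one group, 0.78 with quantile normalization and 0.14 to 0.57 without 1 array, the lowest and highest without MiaPaca2 replicates 1 and 2. ZEB1 was higher by 1.44, a call lost without MiaPaca2 replicate 1 (1.05) or Panc1 replicate 4 (1.27), and when the 3 MiaPaca2 arrays formed one group (0.87). Among 34 coagulation and fibrinolysis genes, THBD was at -6.37, TFPI2 at -3.71, the protein C receptor gene PROCR at -2.58 and PLAU at -1.74, in a list with 5 lower and 2 higher. The PLAU call was lost with the most variable feature of each gene (-1.64, limma, adjusted p = 0.05139). The higher members were F2R and TFPI, the latter by 1.2 with its call lost without MiaPaca2 replicate 1 (0.89) or either Panc1 array (1.02 and 1.38). PLAUR differed by 0.78 without passing (limma, adjusted p = 0.3531), with 0.38 without MiaPaca2 replicate 1 and 1.18 without replicate 2.

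Chemokine genes went both ways between these lines, 9 of 23 members of the NF-kB list being higher in MiaPaca2 and 3 lower. CXCL5 was higher by 3.24, and CCL2 and ICAM1 were at -6.80 and -4.55. The epithelial and NF-kB lists each had a camera adjusted p = 0.03923. Each had an adjusted p = 0.99 with an estimated correlation, and neither passed when arrays were shifted to a median of 0 or quantile normalized. No other list passed. They had 9 of 27 EGFR and MAPK genes higher and 5 lower, 5 of 29 stress genes higher and 4 lower, 3 of 24 hypoxia genes higher and 4 lower, 2 of 23 interferon genes higher and 5 lower, and 2 of 29 proliferation genes higher and 1 lower. Wnt targets had 1 of 18 higher and 3 lower, pancreatobiliary and gastric genes 2 of 29 higher and 2 lower, exocrine and endocrine genes 2 of 19 lower, intestinal genes 1 of 26 lower, and differentiated tissue genes none. Named members included EPHA4, higher by 5.56, AKR1C1 by 3.86 and APCDD1 by 2.46, and GDF15 at -5.03, BNIP3 at -4.61 and CYP1B1 at -4.34. The hypoxia and Wnt lists had a mean and median below 0 but a camera test directed upward, and the stress list had a mean of -0.12, a median of 0.24 and an upward test. With quantile normalization the means of the stress, Wnt, differentiated tissue and pancreatobiliary lists turned above 0, to at most 0.082, and the medians of the coagulation, hypoxia, differentiated tissue and pancreatobiliary lists turned to 0.013, 0.012, 0.065 and 0.018. The hypoxia median and the pancreatobiliary mean also turned with arrays shifted to a median of 0, to 0.00025 and 0.020. Adjusted over the list alone, 4 epithelial genes were higher and 12 lower, 7 stress genes higher and 6 lower, 10 NF-kB, 10 EGFR and MAPK and 4 hypoxia genes were higher, 1 pancreatobiliary and no intestinal gene was lower, and other counts were as given. The dehydrogenase gene ALDH1A1 was higher by 6.95, CAVIN2 by 6.50, UCA1 by 5.90 and TLR8-AS1 by 5.57, and SUSD5, DDX43, TRIM6 and TSPYL5 were at -6.96, -6.93, -6.58 and -6.49. KRTAP4-3 was higher by 5.67 with an SE of 1.15 and was not called with robust eBayes (limma, adjusted p = 0.1048), and was 3.60 without MiaPaca2 replicate 1. In all, 3422 genes were called, 1357 higher and 2065 lower. Without Panc1 replicate 1 the count was 1661, and without Panc1 replicate 4 it was 1656.

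Within MiaPaca2, 55 genes were higher with the DMSO label than without a media label and 55 were lower. This comparison set 2 arrays against 1, and the lone array was assumed to vary like the DMSO-labelled pairs. ARMC12 was at -7.97 and PHACTR3 at -6.76 (limma, adjusted p = 4.233e-05 and 0.002342), each read by a single feature. SRPX, DPH6 and H2AP were at -3.86, -3.85 and -3.59. SLITRK5, the sialomucin gene PODXL, the interleukin receptor gene IL6R, SLFN5 and MCTP1 were higher by 3.20 to 4.06. The keratin gene KRT8 was higher by 1.82, the tight junction gene OCLN by 1.85 and the cytochrome gene CYP1B1 by 2.14, and the transcription factor gene ELF3 was at -3.16 and COL3A1 at -2.79. With their most variable feature, KRT8 (1.40) and OCLN (1.94) were not called (limma, adjusted p = 0.08585 and 0.05089). The differences of the 5 COL3A1 features ran from -4.35 to -0.36. Without DMSO replicate 1, which leaves 1 array against 1, the calls of SLITRK5, PODXL, SLFN5, KRT8, OCLN, CYP1B1, ELF3 and COL3A1 were lost at differences of 4.13, 3.09, 2.82, 1.79, 1.77, 2.03, -2.80 and -2.28. VIM, ZEB1 and PLAU differed by 1.38, 1.71 and 2.01 without passing (limma, adjusted p = 0.09304, 0.08982 and 0.06833). ZEB1 passed without DMSO replicate 2 (2.11, adjusted p = 0.04804). CDH1, EPCAM, TFPI and PLAUR differed by 0.75, 0.72, -0.85 and 1.26 without passing (limma, adjusted p of 0.2901 to 0.3592). With quantile normalization CDH1 and EPCAM were 0.14 and -0.18, and TFPI was -0.023 with its most variable feature and -0.53 without DMSO replicate 2. The count of 110 genes was 24 without DMSO replicate 1, 243 without DMSO replicate 2 and 408 when only these 3 arrays were fitted. In that last fit the error came from the DMSO pair alone, so its calls, ZEB1 and PLAU among them, show nothing about the spread of the lone array. With quantile normalization 32.4% of the called genes were higher, against 50%.

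Of the 14 lists, 6 passed the camera test upward, though CYP1B1 was their sole gene called over all genes. These shifts rest on the 1 array without a media label, and 12 of the 14 list medians were above 0, so a property of that array would give the same result as the DMSO label. NF-kB targets and chemokines had a median difference of 0.69 (adjusted p = 5.832e-05), and Wnt targets 0.51 (adjusted p = 0.00547). With an estimated correlation both had an adjusted p = 0.2742. No member of either list was called over all genes, whereas 7 of 23 NF-kB genes were higher when adjusted over the list alone. Adjusted over the list alone, 5 EGFR and MAPK, 5 mesenchymal, 4 interferon, 4 stress, 4 epithelial, 2 coagulation and 2 hypoxia genes and 1 pancreatobiliary gene were higher, and 2 epithelial genes and 1 mesenchymal gene lower. The coagulation, EGFR and MAPK, interferon and stress lists had adjusted p of 0.004907 to 0.01501, and an adjusted p of 0.3893 to 0.4656 with an estimated correlation. Quantile normalization left 2 lists past the threshold, and it turned the means of the differentiated tissue list, 0.20, and the intestinal list, 0.018 with a median of -0.025, to -0.10 and -0.085. The medians of the epithelial, mesenchymal, pancreatobiliary and differentiated tissue lists also turned, from 0.35, 0.25, 0.18 and 0.28 to -0.040, -0.12, -0.036 and -0.16. The epithelial list had 3 of 29 genes higher and 1 lower, the mesenchymal list 1 of 30 lower, and the other lists had none beyond CYP1B1. F3 was higher by 1.05 without passing (limma, adjusted p = 0.1761).

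Across line means, 4 genes were higher in the 5 pancreatic than in the 3 colorectal lines and none was lower. NR3C1, the glucocorticoid receptor gene, differed by 3.62 (SE 0.383), the zinc finger gene ZNF285 by 2.89 (SE 0.276) and the noncoding RNA gene IPW by 2.75 (SE 0.29), each with a limma adjusted p = 0.04841. C2orf74, which falls outside the rule for named genes and was chosen after its values were seen, differed by 3.65 (SE 0.384, limma, adjusted p = 0.04841). At an unadjusted p under 0.05 there were 1492 genes. All 4 calls were lost without Capan2, HPAC, Panc1, HT29 or SW620, and 1 remained without HPAFII, MiaPaca2 or HCT-116, while the differences without 1 line stayed at 3.30 to 4.05 for NR3C1, 2.75 to 3.04 for ZNF285 and 2.61 to 2.91 for IPW. No gene was called with robust eBayes, with the DMSO label as a covariate or with MiaPaca2 taken from its DMSO arrays. F3 differed by 2.46 (SE 2.02) and PLAU by 5.24 (SE 0.904), and neither passed (limma, adjusted p = 0.7856 and 0.2025). The F3 difference was 1.58 without HPAFII and 3.55 without Panc1, the ends of its range over fits without 1 line. TFPI differed by 2.47 and EPCAM by -2.06, with limma adjusted p of 0.574 and 0.84, the former 1.32 without SW620 and 3.65 without HT29, the latter -2.85 without Capan2 and -0.39 without MiaPaca2. CDH1, VIM, ZEB1 and PLAUR differed by 0.18, 1.66, 0.47 and 1.06 with limma adjusted p of 0.7786 to 0.9893, and CDH1 was below 0 with quantile normalization. Without 1 line they ran from -1.22 (SW620) to 1.56 (MiaPaca2), 0.67 (Panc1) to 2.52 (SW620), 0.018 (MiaPaca2) to 0.83 (SW620) and 0.25 (SW620) to 1.47 (HT29). No list member was called over all genes, and 2 interferon genes and 1 coagulation gene were higher adjusted over the list alone. NF-kB targets and chemokines, the interferon list and the proliferation list were higher and Wnt targets lower in the camera test (adjusted p = 5.472e-07, 5.896e-06, 0.001874 and 0.0003482), and each had an adjusted p = 0.5971 with an estimated correlation. The NF-kB means did not overlap by origin, the lowest pancreatic one being -0.50 in Panc1 and the highest colorectal one -0.68 in HCT-116. The medians of that list did overlap, at -0.91 in Panc1 and -0.82 in HCT-116. Its means on the HT29 arrays alone were -0.71 and -1.05, farther apart than the means of Panc1 and HCT-116. In the other lists that passed, single lines stood apart. The Wnt mean was 1.16 in SW620 and at most -0.073 elsewhere, HCT-116 at -0.84 being below HPAC at -0.30 and Panc1 at -0.70. The interferon means of Panc1 and MiaPaca2, -0.33 and -0.79, lay below the 0.29 of HT29, and the proliferation mean was -0.61 in HCT-116 and at least -0.15 elsewhere. The other 10 lists had adjusted p of 0.1407 to 0.9905. The epithelial list had a median of 0.12, or -0.33 with quantile normalization, and a mean of -0.11, and the coagulation list a median of -0.05 and a mean of 0.51.

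**Figure D3:**
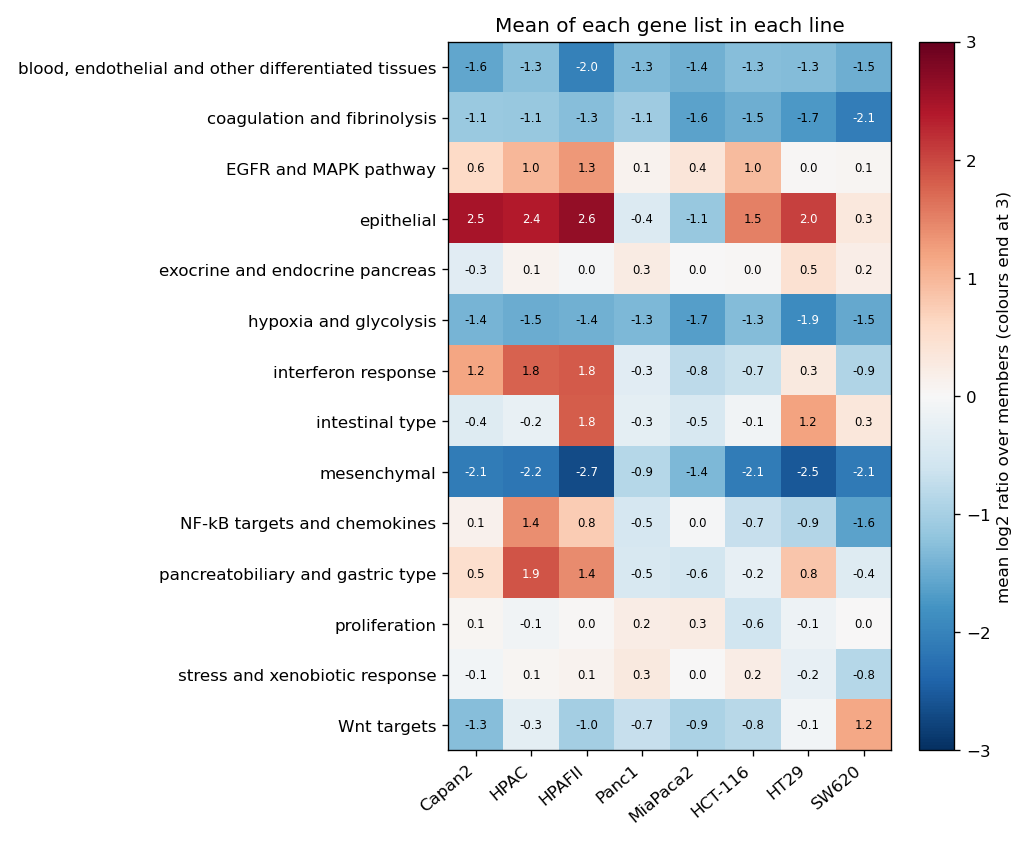
Rows are the gene lists and columns the 8 cell lines, and colour and printed value give the mean log2 ratio over the measured members, with MiaPaca2 as the mean of its 3 arrays. The epithelial list is below 0 in Panc1 and MiaPaca2 alone, and the intestinal list is highest in HPAFII at 1.81 and HT29 at 1.21.

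CDX2 and MUC5AC, genes of intestinal and gastric lineage, did not pass in any limma comparison, with log2 differences of -0.51 to 0.28, although with its most variable feature MUC5AC passed against HT29 in Panc1 (-1.47) and MiaPaca2 (-1.50). By origin, MUC5AC stood at 0.014 without HPAC and CDX2 at -0.16 without HPAFII. F2RL1 was not analysed here.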

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

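Among 27 values looked at over the 5 pancreatic lines, 3 had 1 line far from the others, and chance alone puts about 1 in 20 such groups past the limit. The tests on the spread against the other pancreatic lines, on the spread against all lines and on list members above their HT29 level were chosen after the result was seen, as was the bound of 5 members in the last. The intestinal list mean was 1.81 in HPAFII and -0.49 to -0.23 in the other 4 lines (gap over range 0.889). CDX2 was 2.62 in HPAFII and 0.93 to 1.02 in the others (0.946). MUC5AC was 1.41 in HPAC and at most 0.20 in the other 4 pancreatic lines (0.842), and its 4 features disagreed in sign in several comparisons.

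In the high intestinal list of HPAFII, CDH17 stood at 7.21 and KRT20 at 5.88, while TFF3 at -2.60, MYB at -4.35, NOX1 at 0.60 and REG4 at 0.89 were the 4 of 26 members over 1 below HT29. The HPAFII array had the widest spread of ratios (SD 1.54). With arrays scaled to an equal SD the list mean was 1.36 above the highest other pancreatic line, against at most 0.353 between arrays of a group. Scaling keeps signs, and the list mean was above 0 in HPAFII and below 0 in the other pancreatic lines. The scaled gap therefore could not close, and it does not test the spread. The opposite signs of the means are not what a mere stretch of the ratios around 0 would give. The list medians showed no such contrast of signs. They were 2.25 in HPAFII and 0.047 (MiaPaca2) to 0.24 (Panc1) in the other pancreatic lines, all above 0. Against HT29 the scaled gap was 0.212, within the 0.353 between arrays of a group, so there the spread cannot be told apart. RNA of HT29 in the sample stays partly open. Of 23 HT29 genes, 52.2% were also raised in HPAFII (exact 95% interval 30.6 to 73.2), between the bounds set beforehand. That interval takes genes as independent, which they are not. By contrast, 7 list members stood over 1 scaled unit above their HT29 level, which such RNA could not give. A wrong label or an intestinal character of the line was not tested.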

How the results depend on the processing

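Taking exact zeros as missing and both rescalings of the count of 15 differentiated tissue genes below 0 were chosen after seeing the data. So were the fits of the 6 DMSO-labelled arrays alone. None moved a count past 1.5 times. The fit of those 6 arrays without a block could move none, because its error comes from the same pairs as in the main fit. The F3 differences kept direction and side of the threshold in every setting run. With the replicate number as a replicate block among the 6 DMSO-labelled arrays, which leaves 1 residual degree of freedom, 5520 genes were called for Panc1 against HT29, 4704 for MiaPaca2 against HT29 and 2414 for MiaPaca2 against Panc1, against 6831, 5851 and 3422 without it. Deviations of same-numbered arrays correlated across genes at 0.144, -0.0098 and -0.134, so the numbers were not taken to pair the arrays. The filter on genes with a value on all 12 arrays removed none, F3 had 1 feature, and the fits of genes and lists on F3 were not run. Where no cause is named below, the cause was not tested. Called genes ranged over fits without 1 array from 4135 to 6001 for Panc1 against HT29, 1656 to 3035 for MiaPaca2 against Panc1 and 24 to 243 between MiaPaca2 labels, and without 1 line from 0 to 3 for origin. The 110 MiaPaca2 genes became 62 among variable genes (fewer tested) and 408 from 3 arrays alone, and under quantile normalization 32.4% rather than 50% of calls were higher. The 4 origin genes became 15 with quantile normalization (73.3% higher rather than 100%), 14 with line as a random block, and 0 with robust eBayes, with MiaPaca2 from 2 arrays or with the DMSO covariate. With an estimated correlation, lists past the threshold went from 5, 7, 2, 6 and 4 to 0 in the 5 comparisons. That form of the test has few degrees of freedom, so the loss cannot be laid to correlation alone. Wnt targets, with an estimated correlation of -0.049, went from p = 0.02348 to p = 0.09164 in Panc1 against HT29 (camera). That list had not passed at the preset correlation. The 5 lists that had passed there had estimated correlations of 0.078 (mesenchymal) to 0.32 (intestinal), above the preset 0.01. A part of correlation in their loss is therefore not excluded. For MiaPaca2 against Panc1, lists past the threshold were also 0 with medians at 0 or quantile normalization, and between MiaPaca2 labels 2 with quantile normalization. Quantile normalization moved F3 to 5.31 in Capan2, 5.22 in HPAC, 5.12 in HPAFII and 2.19 in HCT-116, and Panc1 F3 ran from -1.33 to -0.74 without 1 array. Signs turned for uncalled genes and for 1 called gene, ALB in MiaPaca2 against HT29 (0.75 to -0.071 with quantile normalization). TFPI in Panc1 against HT29 was 0.45 with the most variable feature and -0.47 to 0.22 without 1 array. PLAUR in MiaPaca2 against HT29 was -1.37 to 0.29 without 1 array. Against Panc1, VIM was -0.10 with MiaPaca2 as one group and MUC5AC -0.21 to 0.10 without 1 array. Between MiaPaca2 labels, EPCAM was -0.18 with quantile normalization and MUC5AC 0.23 with the most variable feature and -0.25 to 0.060 without 1 array. By origin, CDH1 was -0.31 with quantile normalization, -0.29 with line as a random block and -1.22 to 1.56 without 1 line, and CDX2 was -0.079 with quantile normalization, -0.030 with the most variable feature, and -0.16 to 0.26. Of called named genes besides F3, 47 of 49, 44 of 50, 34 of 49, 7 of 15 and 0 of 3 kept their call throughout. Without intensities, signal over background is unknown and limits what dim features show.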

Other observations

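Capan2, HPAC and HPAFII, each on 1 array, had the highest interferon list means, and the lists and genes named here and for SW620 were chosen after their values were seen. The interferon list means were 1.17, 1.78 and 1.85, against 0.29 in HT29 and below 0 in the other 4 lines, with MX1 at 2.10, 3.12 and 2.56. The ductal keratin KRT7 was 3.32 to 4.45 and the mucin MUC1 2.75 to 3.01 in these lines, and at most -0.019 and 0.048 in the others. Other members of the pancreatobiliary list went the other way in Capan2, with S100P at -3.48 and LYZ at -2.53 against 1.85 and 4.65 in HT29, and its list mean, 0.51, lay below the 0.84 of HT29. PLAT, the tissue plasminogen activator, was 4.62 in Capan2 and 5.35 in HPAC, yet -4.02 in HPAFII and at most -2.09 in the remaining lines. THBD was 2.61 to 4.47 in Capan2, HPAC, HPAFII and Panc1 and at most -2.41 elsewhere. These are values without a test.

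SW620 had the highest Wnt list mean, 1.16, with AXIN2 at 3.01, NKD1 at 2.81, LGR5 at 1.73 but another member, CD44, at -3.63. It also had the lowest TFPI, -4.20, and the lowest F2R, -4.42. Its CDH1 was -2.86 while EPCAM was 2.78. CFTR was 3.42 in HT29 and at most -1.35 in every other line.

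The tests of a shared batch, of erratic features and of other splits were set before their results were seen. The 110 genes called between MiaPaca2 arrays may partly reflect a batch shared by arrays without a media label rather than DMSO. Of these genes, 72.7% differed the same way between the mean of HT29 and Panc1 and the mean of the 5 other lines without a media label (exact 95% interval 63.4 to 80.8), against 58% of all genes. No MiaPaca2 array enters that test, but line and label are confounded in it, and an effect of the DMSO label would give the same sign. Its interval takes genes as independent although they share the same few lines, so it gives no spread over lines or arrays. For erratic single features, 1-feature genes were 1.04 times as frequent among called as among all genes, so calls were hardly enriched for them. Of 44 called genes with several features, 42 had all of them on one side. Calling on large mean differences favours such agreement, and no share over all genes was taken. It also says nothing about the 60% of called genes read by 1 feature, for which erratic features stay open. ARMC12, 7.58 on the MiaPaca2 array without a media label and at most 0.46 on the other 11, remains a single feature on a single array.

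Chance could not be excluded for the 4 genes called between pancreatic and colorectal lines. Of the 56 splits of 8 lines into 5 and 3, 7 called at least as many genes, the real split included. The highest other split called 33. That split, Panc1, MiaPaca2 and SW620 against the rest, was singled out after the counts were seen. A count several times the real one may reflect a structure of the lines, which was not tested.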
